A study of Mus musculus with 8 samples.

How the data were processed

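RNA was measured in 8 libraries from cells of whole C57BL/6J mouse brain that had been sorted magnetically with the anti-GLAST (ASCA-1) antibody. GLAST is the glutamate transporter encoded by Slc1a3 and is carried by radial glia and astrocytes. The labels give 4 libraries from postnatal day 0 (P0), which they name radial glia, and 4 from postnatal day 8 (P8), which they name astrocyte precursors. Per the labels' protocols, tissue was dissociated enzymatically and mechanically, RNA was isolated with the PicoPure kit and libraries were made with the TruSeq RNA kit v2, a kit that does not mark strand. TopHat and the mouse build mm9 are named in the submitters' processing notes, without versions or settings. The read counter and the gene annotation are not given in the sources used here. The labels do not say whether the replicates of an age were separate animals, litters or pools, so the p-values measure only the spread between these libraries. Part of that spread may be technical, although Xist and Y-linked genes argue against replicates of a single pool (see Results).

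The authors deposited 1 table of 23284 genes, with whole-number counts per gene and library under the header "count". The deposited CPM values equalled each count divided by its column total, and the deposited RPKM values equalled CPM divided by the gene length in kilobases, both to a relative difference under 5e-12. The table also carries the authors' own comparison of P8 with P0 (log2 fold change, mean log2 CPM, p-value and false discovery rate) for 15546 genes, per the file headers. The remaining genes have no value there. No symbol was empty or repeated, and 3225 genes had no read in any library. Column names in the table give the age and replicate number of each library, and no column of per-sample values was left without a library.

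Total counts ranged from 30708719 to 94308235 per library. At these depths 3 counts, the most that a true level could give while being missed at a count of 0, correspond to between 0.0318 and 0.0977 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was identical. Within an age, every pair differed by far more than sampling noise, with a chi-square per degree of freedom of at least 76.4 over genes with at least 10 counts in the pair.

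The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16808 genes. Normalization was by TMM, the fit by glmQLFit and the two-sided test by glmQLFTest, with all 8 libraries and no covariate. Adjustment was by the Benjamini-Hochberg method over all genes tested, and genes were called at an adjusted p under 0.05. Standard errors are those implied by the F statistic. Levels are given as CPM, mean ± SD over the 4 libraries of an age, and fold changes come from the edgeR fit. The dispersion common to all genes corresponded to a biological coefficient of variation of 30.6%. The 34 gene lists (pathways, lineages and markers of the cell types that the sort could hold) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at the preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the 34 lists. The same scripts were tested on simulated data made from the means and library sizes of this comparison. Of 200 changed genes among 16675, the test recovered 47% of 2-fold and 98% of 4-fold changes and called 10 unchanged genes. The changed list was called and 0 unchanged lists were. Genes were simulated independently of each other. The simulation therefore does not show how often camera calls unchanged lists whose members vary together. It also changed a far smaller share of genes than the 49.5% called in the data. Its rates are therefore not those of this comparison, and TMM was not tested with so many genes changed.

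The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names 7 genes always, and the 12 genes with the largest rise and the 12 with the largest fall among called genes whose ages do not overlap and whose higher mean is at least 10 CPM, with predicted and sex-linked genes passed over (0 were). It also names up to 4 called members of each list with the largest change and a mean of at least 1 CPM, or the highest member where none was called, and the 5 genes with the highest mean at each age. Further members that moved against their list may be named. The rule gave 219 genes, and the text names part of them. Some genes that the rule gives are not reported here. Positions are spans of the GENCODE M1 annotation of NCBIM37, the assembly that mm9 stands for. They were matched by symbol, with 217 of the 219 genes matched to 1 annotated gene. Exons of 21 named genes overlap an exon of another protein-coding gene. Because the kit does not mark strand, reads there could have been assigned to either gene, and values of these genes are uncertain by that amount.

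The alternatives were the replicate number as a block, leaving out each library in turn, no filter beyond 1 read, a mean of at least 5 CPM, DESeq2 size factors in the edgeR fit, library totals without the erythroid genes and the 20 genes with the highest mean, the Wald test of DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, and an estimated correlation in the list tests. With DESeq2 the lists were tested by the preranked form of camera on the Wald statistics, so its list calls differ in the list test as well. Leaving out P0 2 and P8 2 together was added after seeing the data. Alternatives written for tables of normalized values were not run, since counts were deposited. The RPKM values were checked and not used further.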

Results

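Transcript counts were obtained from cells of whole mouse brain sorted for GLAST at birth and in the second postnatal week. There were 4 libraries at P0 and 4 at P8, named here by age and replicate number (P0 1 to P0 4 and P8 1 to P8 4). Total counts were 48701066, 30708719, 54615722 and 53916938 in P0 1 to P0 4, and 94308235, 70284047, 63131890 and 63695553 in P8 1 to P8 4. Between 16992 and 18666 genes had at least 1 read in a library. The labels name the P0 cells radial glia, the progenitors that line the ventricles of the developing brain, and the P8 cells astrocyte precursors. The comparison addresses which transcripts differ between these sorted populations. No unsorted or GLAST-negative library was included, so enrichment for GLAST-positive cells was not tested at either age. At P0 the mean log2 CPM was 5.54 for the radial glia list, 7.96 for the choroid plexus list and 7.29 for the endothelial list. Each list holds different genes, so these means do not measure shares of cells.

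Slc1a3, which encodes the sort antigen GLAST, was read in every library and was higher at P8. It stood at 228, 300, 331 and 323 CPM in P0 1 to P0 4 and at 3919, 5029, 3867 and 3718 CPM in P8 1 to P8 4. The mean rose from 296 ± 46.8 to 4133 ± 603 CPM (SD, n = 4), a log2 fold change of 3.90 with a standard error of 0.20 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.21e-06). Slc1a3 lies on chromosome 15 at 8584124 to 8660764 on the minus strand (NCBIM37). Nes, which encodes the progenitor intermediate filament nestin, rose from 83.4 ± 12.5 to 134 ± 18.1 CPM (edgeR adjusted p = 0.0022). The proliferation marker Mki67 rose from 99.6 ± 15.1 to 147 ± 19.6 CPM (edgeR adjusted p = 0.00456).

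The ages differed in close to 1 of every 2 tested genes. Of 16808 genes, 8321 (49.5%) were called by edgeR at an adjusted p under 0.05, 4111 higher and 4210 lower at P8. A change of at least 2-fold was estimated for 2480 of the higher and 2811 of the lower genes, and a change of at least 16-fold for 241 and 410. The median log2 fold change of tested genes was 0.044. The 4 libraries of one age did not overlap those of the other for 7928 genes (47.2%), against 2.86% by chance. The first principal component held 74.5% of the variance of log2 CPM and separated the ages, and the second (8.87%) set P0 2 apart from P0 1. Correlations of log2 CPM across genes were 0.938 to 0.976 within P0, 0.964 to 0.985 within P8 and 0.788 to 0.869 between ages. In the authors' deposited table, 7560 of 15546 genes had a false discovery rate under 0.05, 3765 higher and 3795 lower at P8. Among the 15527 genes tested in both the authors' deposited table and here, 7136 were called in the same direction and 0 in opposite directions. A further 874 were called only here and 405 only in the authors' deposited table. The log2 fold changes of the 2 sources had a correlation across genes of 0.999.

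The most abundant transcripts changed with age. At P0 the highest mean belonged to Ttr, which encodes the thyroid hormone carrier transthyretin and is a marker of the choroid plexus, the epithelium that makes cerebrospinal fluid. Ttr stood at 37740 ± 17400 CPM at P0 and at 1242 ± 1210 CPM at P8 (edgeR adjusted p = 0.000791), and took between 2.29% and 6.17% of the counts of a P0 library. Its P8 mean without P8 4 was 660 CPM. It lies on chromosome 18 at 20823751 to 20832825 on the plus strand. Eef1a1, Ptgds, Fn1 and Enpp2 were also among the 5 highest means at P0. Of these, Ptgds (prostaglandin D2 synthase) fell from 5441 ± 4410 to 63.0 ± 20 CPM, Fn1 (fibronectin) from 4909 ± 2090 to 455 ± 155 CPM and Enpp2 (autotaxin) from 3902 ± 1020 to 350 ± 200 CPM. Ptgds stood at 11820 CPM in P0 1, its P0 mean without that library was 3313 CPM, and it was below Fn1 and Enpp2 in P0 2 and P0 3. Eef1a1, a translation elongation factor, was at 5594 ± 1090 and 4174 ± 309 CPM (edgeR adjusted p = 0.16), and was called lower without P0 2 (edgeR adjusted p = 0.0493). Among the highest means at P8 were those of Apoe (the main lipid carrier made by astrocytes), Sparcl1, Scd2 and Cpe. Apoe rose from 2473 ± 687 to 10440 ± 1960 CPM, Sparcl1 from 833 ± 75 to 6707 ± 876 CPM and Cpe from 370 ± 39.3 to 6252 ± 1040 CPM.

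Astrocyte genes rose together. Of 31 tested astrocyte markers 29 were higher at P8, 1 was lower and 1 did not pass, both over all genes tested and adjusted over the list alone, with a median rise of 9.26-fold (camera adjusted p = 2.04e-14; adjusted p = 0.106 with an estimated correlation). Gpr37l1, an orphan receptor of astrocytes, rose from 3.26 ± 0.77 to 645 ± 56 CPM, and the neurotensin receptor gene Ntsr2 from 0.73 ± 0.23 to 106 ± 13.5 CPM. The water channel gene Aqp4 rose from 27.9 ± 8.31 to 1519 ± 151 CPM (log2 fold change 5.85, standard error 0.27, edgeR adjusted p = 1.47e-06). Slc1a2, which encodes the glutamate transporter GLT-1, rose from 69.98 ± 28.4 to 4546 ± 627 CPM (log2 fold change 6.11, standard error 0.38, edgeR adjusted p = 3.85e-06). The intermediate filament gene Gfap rose from 20.8 ± 11.2 to 756 ± 108 CPM, and the folate enzyme gene Aldh1l1 from 127 ± 30 to 862 ± 36.2 CPM. Aqp4 lies on chromosome 18 at 15547903 to 15562193, Slc1a2 on chromosome 2 at 102498816 to 102630941 and Gfap on chromosome 11 at 102748650 to 102762226. The connexin 30 gene Gjb6 went the other way, from 167 ± 92.9 to 31.6 ± 2.99 CPM. In the same libraries the choroid plexus, vascular and meningeal lists moved down with age.

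**Figure D1:**
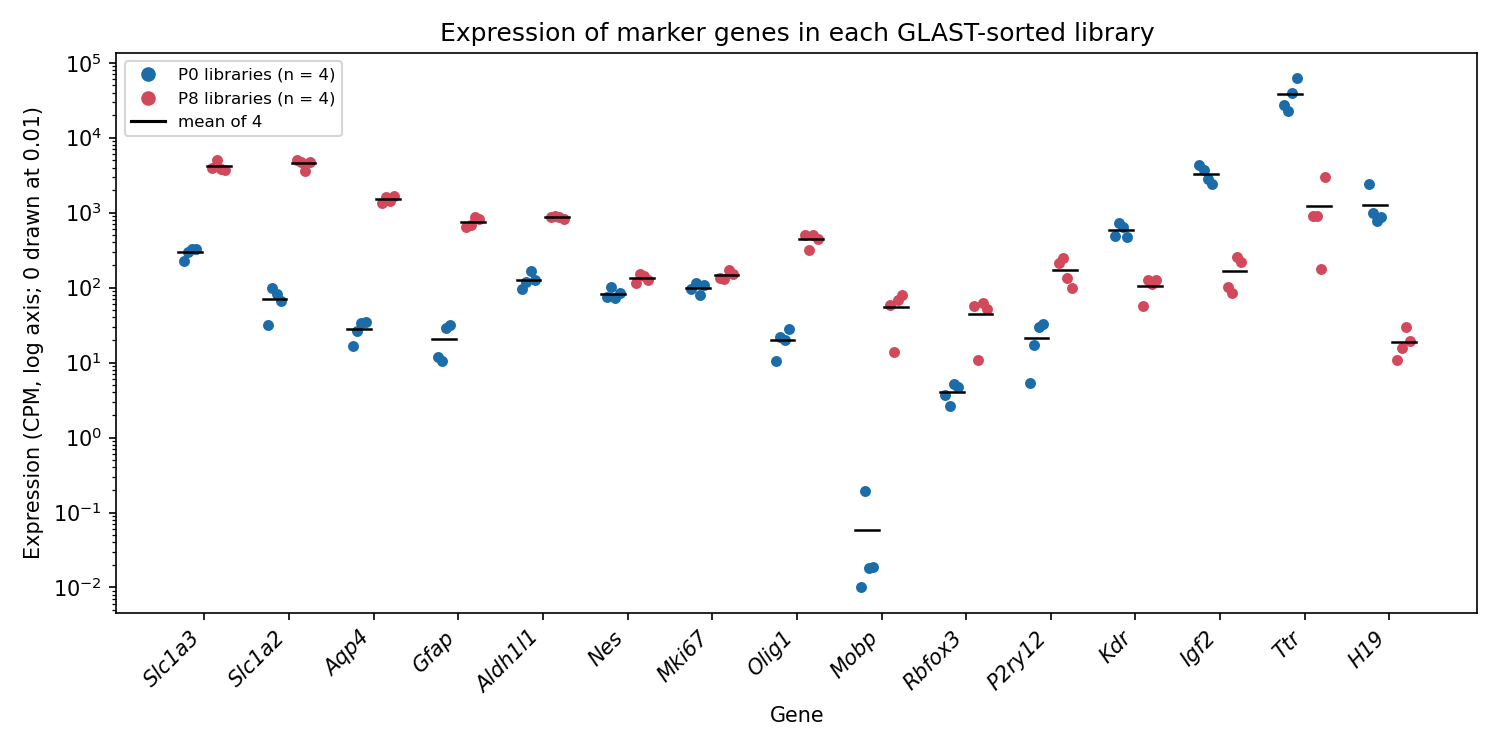
Expression of 15 named genes in each library, in CPM on a log axis, with 1 point per library, P0 in blue and P8 in red, and a bar at the mean of 4. All 4 P8 libraries lie above all 4 P0 libraries for Slc1a3 (3718 CPM and more against 331 CPM and less), and Ttr, Igf2, Kdr and H19 go the other way.

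Radial glia genes were also higher at P8. Of 22 tested markers 17 rose and 2 fell, with the same counts adjusted over the list alone and a median rise of 3.97-fold (camera adjusted p = 3.82e-05; adjusted p = 0.483 with an estimated correlation). Ptprz1, a receptor phosphatase of radial glia and glial precursors, rose from 318 ± 78.3 to 5225 ± 362 CPM. The transcription factor genes Pax6 and Nr2e1 rose from 15.9 ± 7.83 to 120 ± 30.6 CPM and from 8.19 ± 3.49 to 57.0 ± 5.86 CPM. An exon of Pax6 overlaps Elp4 on the other strand. Hes1, an effector of Notch signalling, fell from 50.1 ± 14.2 to 16.9 ± 4.79 CPM, and the intermediate filament gene Vim from 983 ± 313 to 479 ± 77.2 CPM. Gliogenic transcription factors gave 13 higher and 2 lower of 20 (14 and 2 adjusted over the list alone), with a median of 2-fold (camera adjusted p = 0.00401; adjusted p = 0.483 with an estimated correlation). Olig2 rose from 8.56 ± 4.81 to 91.9 ± 28.2 CPM, Lhx2 from 14.6 ± 8.79 to 101 ± 5.25 CPM and Rfx4 from 17.3 ± 5.7 to 100.2 ± 4.37 CPM. The orphan receptor gene Nr2f2 fell from 103 ± 20.8 to 19.1 ± 4.45 CPM, and Id1, a target of BMP signalling, from 83.6 ± 22 to 32.6 ± 5.92 CPM. The choroid plexus, vascular and meningeal lists fell in the same libraries, by a median of 32.2-fold for choroid plexus markers.

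Cell cycle genes were modestly higher at P8. For DNA replication and the G1/S transition, 22 of 27 tested genes rose and 5 did not pass (23 rose adjusted over the list alone), with a median of 1.73-fold (camera adjusted p = 6.79e-06; adjusted p = 0.483 with an estimated correlation). The helicase subunit gene Mcm5 rose from 41.3 ± 8.97 to 94.9 ± 11.2 CPM, the primase gene Prim1 from 10.1 ± 3.3 to 27.1 ± 3.43 CPM and Gins1 from 5.71 ± 1.79 to 13.4 ± 2.07 CPM. For mitosis and G2/M, 12 of 28 rose and 16 did not pass, with the same count adjusted over the list alone and a median of 1.4-fold (camera adjusted p = 0.00218; adjusted p = 0.613 with an estimated correlation). Among these, the kinetochore gene Nuf2 rose from 16.4 ± 4.61 to 34.8 ± 2.88 CPM and cyclin A2 (Ccna2, which shares an exon position with Exosc9 on the other strand) from 36.3 ± 8.03 to 69.2 ± 14 CPM. Choroid plexus genes fell in the same libraries.

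Transcripts of neurons and their precursors were present and were higher at P8. Intermediate progenitor and neuroblast markers gave 13 higher of 22 and 9 that did not pass, the same adjusted over the list alone (median 2.93-fold, camera adjusted p = 0.00205; adjusted p = 0.592 with an estimated correlation). Insm1 rose from 2.62 ± 2.11 to 33.01 ± 16.2 CPM, and doublecortin (Dcx) from 12.1 ± 8.71 to 95.7 ± 51.3 CPM with overlapping ages. Mature neuron markers gave 16 higher and 1 lower of 19, the same adjusted over the list alone (median 7.33-fold, camera adjusted p = 0.000323; adjusted p = 0.569 with an estimated correlation). Camk2a, a synaptic kinase gene, rose from 4.45 ± 0.81 to 125 ± 97.5 CPM and Rbfox3, which encodes NeuN, from 4.05 ± 1.13 to 45.03 ± 23.2 CPM. The neuronal enolase gene Eno2 went the other way, from 24.1 ± 1.76 to 13.03 ± 4.63 CPM (edgeR adjusted p = 0.0262), a call lost without P0 2 (adjusted p = 0.0563) or without P8 3 (adjusted p = 0.0571). Cerebellar granule lineage markers gave 9 higher and 1 lower of 14, the same adjusted over the list alone (median 2.2-fold, camera adjusted p = 0.0296; adjusted p = 0.569 with an estimated correlation). Barhl1 rose from 1.39 ± 0.72 to 40.7 ± 20.7 CPM and Atoh1, a determinant of granule precursors, from 0.0277 ± 0.0355 to 2.45 ± 1.2 CPM (0.0122 CPM at P0 without P0 4). Zic2 fell from 131 ± 40.8 to 55.8 ± 15 CPM. The mean log2 CPM of the mature neuron list was 2.29 in P8 2, against 4.15 or more in the other P8 libraries and 1.88 or less at P0.

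Oligodendrocyte lineage genes showed some of the largest rises. Myelin and oligodendrocyte markers gave 11 higher and 1 lower of 17 (12 and 1 adjusted over the list alone), with a median of 12.8-fold (camera adjusted p = 0.000121; adjusted p = 0.483 with an estimated correlation). The myelin gene Mobp, on chromosome 9 at 120058860 to 120090602, rose from 0.0581 ± 0.092 to 55.0 ± 28.7 CPM (log2 fold change 10.28, standard error 0.86, edgeR adjusted p = 1.48e-05). Mog rose from 0.126 ± 0.145 to 10.3 ± 6.23 CPM and Mag from 1.80 ± 0.68 to 95.6 ± 49.8 CPM. The P0 mean of Mobp was 0.0123 CPM without P0 2, and that of Mog 0.0572 CPM without P0 4. Cldn11, a tight junction gene of myelin, fell from 482 ± 301 to 47.5 ± 21.5 CPM. Its P0 level was far above those of Mobp, Mog and Mag, and which cells carried it was not tested. Cldn11 stood highest in P0 1 (930 CPM, nearest 381). That library also had the highest pericyte, smooth muscle and meningeal list (mean log2 CPM 7.61, other P0 libraries 6.58 to 6.93). Oligodendrocyte precursor markers gave 12 higher and 2 lower of 17, the same adjusted over the list alone (median 5.93-fold, camera adjusted p = 0.00122; adjusted p = 0.483 with an estimated correlation). Olig1 rose from 20.2 ± 7.31 to 445 ± 91.5 CPM and Gpr17, a receptor gene of differentiating precursors whose exons overlap Lims2, from 5.14 ± 1.14 to 184 ± 133 CPM. Bmp4 fell from 104 ± 34.5 to 4.44 ± 1.3 CPM. The pericyte, smooth muscle and meningeal list fell in the same libraries, by a median of 8.5-fold. Pdgfra was at 444 ± 68.3 and 174 ± 138 CPM with overlapping ages (edgeR adjusted p = 0.0492). Its call was lost in 6 of the 8 fits that left out 1 library, P8 2 and P8 3 being the exceptions, with adjusted p from 0.0614 to 0.115. Without P8 3 its P8 mean was 109 CPM. The myelin and precursor lists were both lowest at P8 in P8 2, where the myelin list had a mean log2 CPM of 4.04 against 5.4 or more.

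Microglia and macrophage genes were higher at P8, and vascular, meningeal, ciliated, choroid plexus and blood cell genes were lower. Of 20 tested microglia markers 18 rose and 2 did not pass (19 rose adjusted over the list alone), with a median of 3.17-fold (camera adjusted p = 0.00056; adjusted p = 0.592 with an estimated correlation). P2ry12 rose from 21.5 ± 12.7 to 173 ± 67.3 CPM and Itgam from 39.6 ± 18.2 to 248 ± 112 CPM. Endothelial markers gave 15 lower and 1 higher of 17, the same adjusted over the list alone, with a median 3.08-fold lower (camera adjusted p = 8.33e-05; adjusted p = 0.497 with an estimated correlation). The VEGF receptor gene Kdr fell from 586 ± 127 to 106 ± 33 CPM and the cadherin gene Cdh5 from 472 ± 104 to 57.3 ± 19.1 CPM. Slco1c1, a thyroid hormone transporter gene of brain endothelium and astrocytes, rose from 132 ± 23.4 to 417 ± 98.8 CPM. Pericyte, smooth muscle and meningeal markers gave 13 lower of 17 and 4 that did not pass, the same adjusted over the list alone, with a median 8.5-fold lower (camera adjusted p = 2.4e-05; adjusted p = 0.483 with an estimated correlation). Igf2 fell from 3319 ± 870 to 164 ± 83.9 CPM and the proteoglycan gene Dcn from 278 ± 145 to 20.1 ± 10.1 CPM.

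All 12 choroid plexus markers fell, with the same count adjusted over the list alone and a median 32.2-fold lower (camera adjusted p = 2e-07; adjusted p = 0.483 with an estimated correlation). The bicarbonate transporter gene Slc4a5 fell from 692 ± 320 to 8.09 ± 7.42 CPM, Clic6 from 1151 ± 373 to 16.6 ± 10.7 CPM and the water channel gene Aqp1 from 828 ± 195 to 13.4 ± 9.84 CPM. Without P8 4 the P8 means of Slc4a5 and Aqp1 were 4.47 and 8.63 CPM. Ependymal and motile cilia markers gave 12 lower and 3 higher of 17 (13 and 3 adjusted over the list alone), with a median 4.54-fold lower (camera adjusted p = 0.0113; adjusted p = 0.595 with an estimated correlation). Spag6, a gene of the ciliary axoneme, fell from 44.0 ± 17.3 to 5.83 ± 2.97 CPM, whereas Tmem212 and Ccdc153 rose from 0.0879 ± 0.132 to 3.99 ± 2.15 CPM and from 0.284 ± 0.22 to 7.04 ± 3.74 CPM (Tmem212 at P0 without P0 4: 0.0244 CPM). Erythroid genes gave 7 lower of 8, the same adjusted over the list alone, with a median 2.99-fold lower (camera adjusted p = 0.00511; adjusted p = 0.483 with an estimated correlation). The band 3 gene Slc4a1 fell from 12.4 ± 6.76 to 0.80 ± 0.58 CPM. The globin genes Hba-a1 and Hba-a2 had identical counts in every library, are near-identical copies and are therefore uncertain, at 186 ± 69.8 and 52.1 ± 17.4 CPM.

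**Figure D2:**
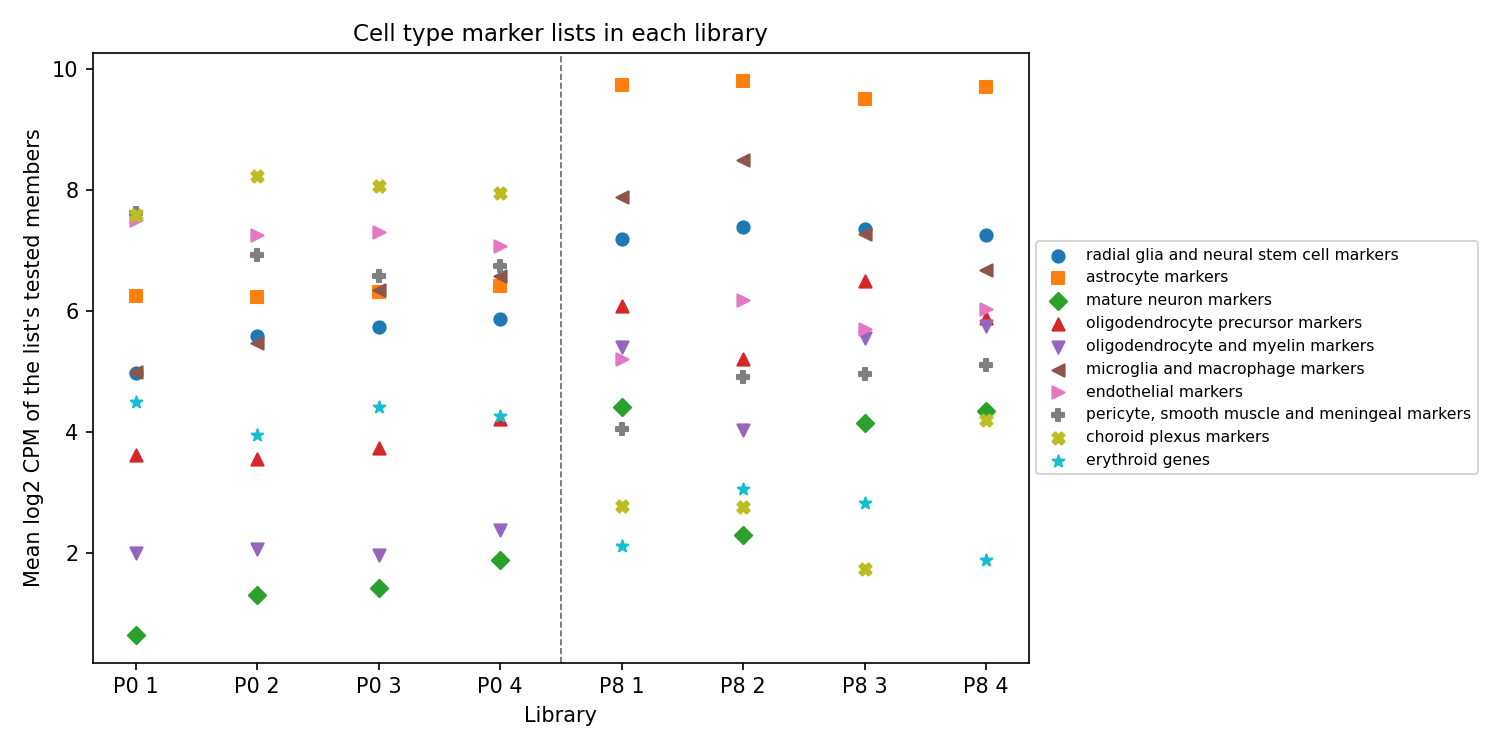
Mean log2 CPM of the tested members of 10 marker lists in each library, with P0 left and P8 right of the dashed line. The choroid plexus list lies at 7.58 or more in every P0 library and at 4.19 or less in every P8 library, and the neuron and oligodendrocyte lists are lowest at P8 in P8 2.

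Cholesterol synthesis genes all rose. Of 23 tested genes 23 were higher at P8, also adjusted over the list alone, with a median of 3.58-fold (camera adjusted p = 2.51e-10; adjusted p = 0.483 with an estimated correlation). The sterol reductase gene Tm7sf2 rose from 18.1 ± 2.17 to 165 ± 17.6 CPM, Sc4mol, the sterol methyl oxidase gene, from 38.7 ± 10.7 to 274 ± 33.3 CPM and Cyp51 from 60.0 ± 12.9 to 382 ± 34.6 CPM. Exons of Tm7sf2 overlap a neighbouring gene on the same strand. Scd2, a fatty acid desaturase gene, rose from 1305 ± 150 to 6541 ± 646 CPM. In the same libraries the choroid plexus, vascular and meningeal lists fell and the myelin list rose by a median of 12.8-fold. Other metabolic lists went both ways. Fatty acid oxidation and ketogenesis gave 7 higher and 5 lower of 26 (6 and 5 adjusted over the list alone), with a median log2 fold change of 0.11 and a mean of -0.0143 (camera adjusted p = 0.839). Acsl6, an acyl-CoA synthetase gene, rose from 33.3 ± 9.42 to 486 ± 38.7 CPM, and its relative Acsl1 fell from 91.6 ± 12.4 to 20.9 ± 2.19 CPM. Glycolysis and glycogen genes gave 8 higher and 5 lower of 25, the same adjusted over the list alone (camera adjusted p = 0.444). The phosphofructokinase genes moved apart, with Pfkm rising from 142 ± 5.27 to 514 ± 52.9 CPM and Pfkp falling from 202 ± 30 to 41.7 ± 6.8 CPM, the latter overlapping Pitrm1 on the other strand. The aldolase gene Aldoc rose from 132 ± 52.2 to 1465 ± 142 CPM.

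Oxidative phosphorylation and ribosomal protein genes differed little beside the spread at P0. Of 31 oxidative phosphorylation genes 4 were higher (1 adjusted over the list alone) and 27 did not pass (camera adjusted p = 0.0764), with Uqcrfs1, a complex III subunit gene, at 49.5 ± 10.3 and 84.2 ± 9.69 CPM. The calls other than that of Uqcrfs1 were each lost without P8 1 (edgeR adjusted p from 0.0603 to 0.115) and in further fits that left out 1 library. None of 33 ribosomal protein genes was called by edgeR, by DESeq2 or by limma-voom, and 0 had an unadjusted edgeR p under 0.05 (camera adjusted p = 0.0834). Rpl3 was at 864 ± 223 and 840 ± 110 CPM. Both lists were called higher by camera without P0 1 (adjusted p = 0.0189 and 0.0489), without P0 4 (0.0213 and 0.00279) or without P8 3 (0.0172 and 0.0224) at the preset correlation, and with an estimated correlation and all 8 libraries the adjusted p was 0.78 for both. The mean log2 CPM of ribosomal protein genes was 7.16 in P0 2 and 8.1 to 9.22 in the other P0 libraries.

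Genes for factors by which astrocytes regulate synapses gave 12 higher and 5 lower of 21 (13 and 5 adjusted over the list alone), with a median of 2.01-fold (camera adjusted p = 0.0145; adjusted p = 0.483 with an estimated correlation). The glypican gene Gpc5 rose from 3.76 ± 1.54 to 112 ± 11.3 CPM and Chrdl1, which encodes a BMP antagonist, from 4.11 ± 1.01 to 104 ± 16.8 CPM. The thrombospondin genes Thbs1 and Thbs2 fell from 245 ± 75.3 to 30.4 ± 8.17 CPM and from 182 ± 7.35 to 21.96 ± 3.42 CPM. Extracellular matrix genes moved apart, with 11 higher and 16 lower of 30 (12 and 16 adjusted over the list alone; camera adjusted p = 0.395), a median log2 fold change of -1.31 and a mean of -0.0531. Those that rose included components of the perineuronal matrix. Bcan rose from 115 ± 44.4 to 2400 ± 163 CPM, Ncan from 255 ± 78.6 to 4319 ± 128 CPM and Hapln1 from 2.54 ± 1.19 to 119 ± 17.4 CPM. The collagen gene Col5a1 fell from 792 ± 223 to 39.5 ± 14.3 CPM, as did most meningeal and vascular markers in these libraries.

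Heterochronic and fetal growth genes fell. Of 17 tested genes 14 were lower and 1 was higher (14 and 2 adjusted over the list alone), with a median 9.58-fold lower (camera adjusted p = 2.46e-06; adjusted p = 0.243 with an estimated correlation). The imprinted RNA gene H19, on chromosome 7 at 149761434 to 149764048, fell from 1265 ± 763 to 19 ± 7.92 CPM (log2 fold change -6.00, standard error 0.50, edgeR adjusted p = 1.48e-05). The imprinted genes Dlk1 and Cdkn1c fell from 123 ± 20.5 to 3.95 ± 1.61 CPM and from 492 ± 261 to 16.4 ± 3.86 CPM. Igf2bp1, a fetal RNA-binding protein gene, fell from 13.9 ± 3.81 to 0.64 ± 0.29 CPM. The imprinted gene Ndn rose from 42.0 ± 7.91 to 71.6 ± 11.1 CPM. Igf2, which counts in this list and in the meningeal list, is also expressed by vascular and meningeal cells, and most other markers of those cells were lower. H19 and Cdkn1c were highest in P0 1 (2400 and 880 CPM, nearest 998 and 398). That library also had the highest pericyte, smooth muscle and meningeal list, and which cells carried these transcripts was not tested.

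Signalling lists were not called as lists by camera on the edgeR fit of all 8 libraries. Notch pathway genes gave 10 higher and 7 lower of 22 (10 and 8 adjusted over the list alone; camera adjusted p = 0.406). The feedback inhibitor gene Nrarp rose from 19.1 ± 2.24 to 125 ± 2.34 CPM, Hes5 from 16 ± 7.35 to 79.0 ± 13.6 CPM and the ligand gene Dner from 21.8 ± 9.82 to 183 ± 26.1 CPM, while Notch2 fell from 685 ± 174 to 143 ± 25.7 CPM. Wnt pathway genes gave 7 higher and 14 lower of 31, the same adjusted over the list alone (camera adjusted p = 0.0834). The ligand gene Wnt7a rose from 3.28 ± 1.78 to 75.1 ± 5.7 CPM and Wnt7b from 8.05 ± 4.7 to 83.4 ± 4.42 CPM, while the R-spondin gene Rspo2 fell from 18.4 ± 7.78 to 0.48 ± 0.17 CPM. BMP and TGF-beta genes gave 6 higher and 12 lower of 27 (7 and 12 adjusted over the list alone; camera adjusted p = 0.0702). The receptor gene Bmpr1b rose from 5.41 ± 2.75 to 75.4 ± 4.83 CPM and Bmp6, which overlaps Txndc5 on the other strand, fell from 165 ± 17.9 to 8.91 ± 4.07 CPM. At the preset correlation this list was called lower without P0 1 (camera adjusted p = 0.0489), P0 4 (0.0378), P8 2 (0.0452) or P8 3 (0.0497) and with no filter (0.0459). With DESeq2 it was also called lower (preranked camera adjusted p = 0.00367, preset correlation). With an estimated correlation and all 8 libraries its camera adjusted p was 0.483. FGF and EGF receptor genes gave 11 higher and 7 lower of 26, the same adjusted over the list alone (camera adjusted p = 0.21), with Fgfr3 rising from 93.4 ± 27.5 to 815 ± 46.3 CPM and Etv4, a transcriptional target of FGF signalling, from 11.9 ± 2.97 to 182 ± 17 CPM. That list was called higher with DESeq2 at the preset correlation (preranked camera adjusted p = 0.0408). With edgeR and an estimated correlation its camera adjusted p was 0.758. Hedgehog genes gave 3 higher and 5 lower of 13, the same adjusted over the list alone, with a median log2 fold change of 0.037, a mean of -0.603 and a downward test (camera adjusted p = 0.406). The receptor gene Ptch1 rose from 96.8 ± 32.9 to 197 ± 22.2 CPM, and the ligand gene Shh fell from 2.58 ± 0.89 to 0.0943 ± 0.0786 CPM (0.0624 CPM at P8 without P8 3).

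**Figure D3:**
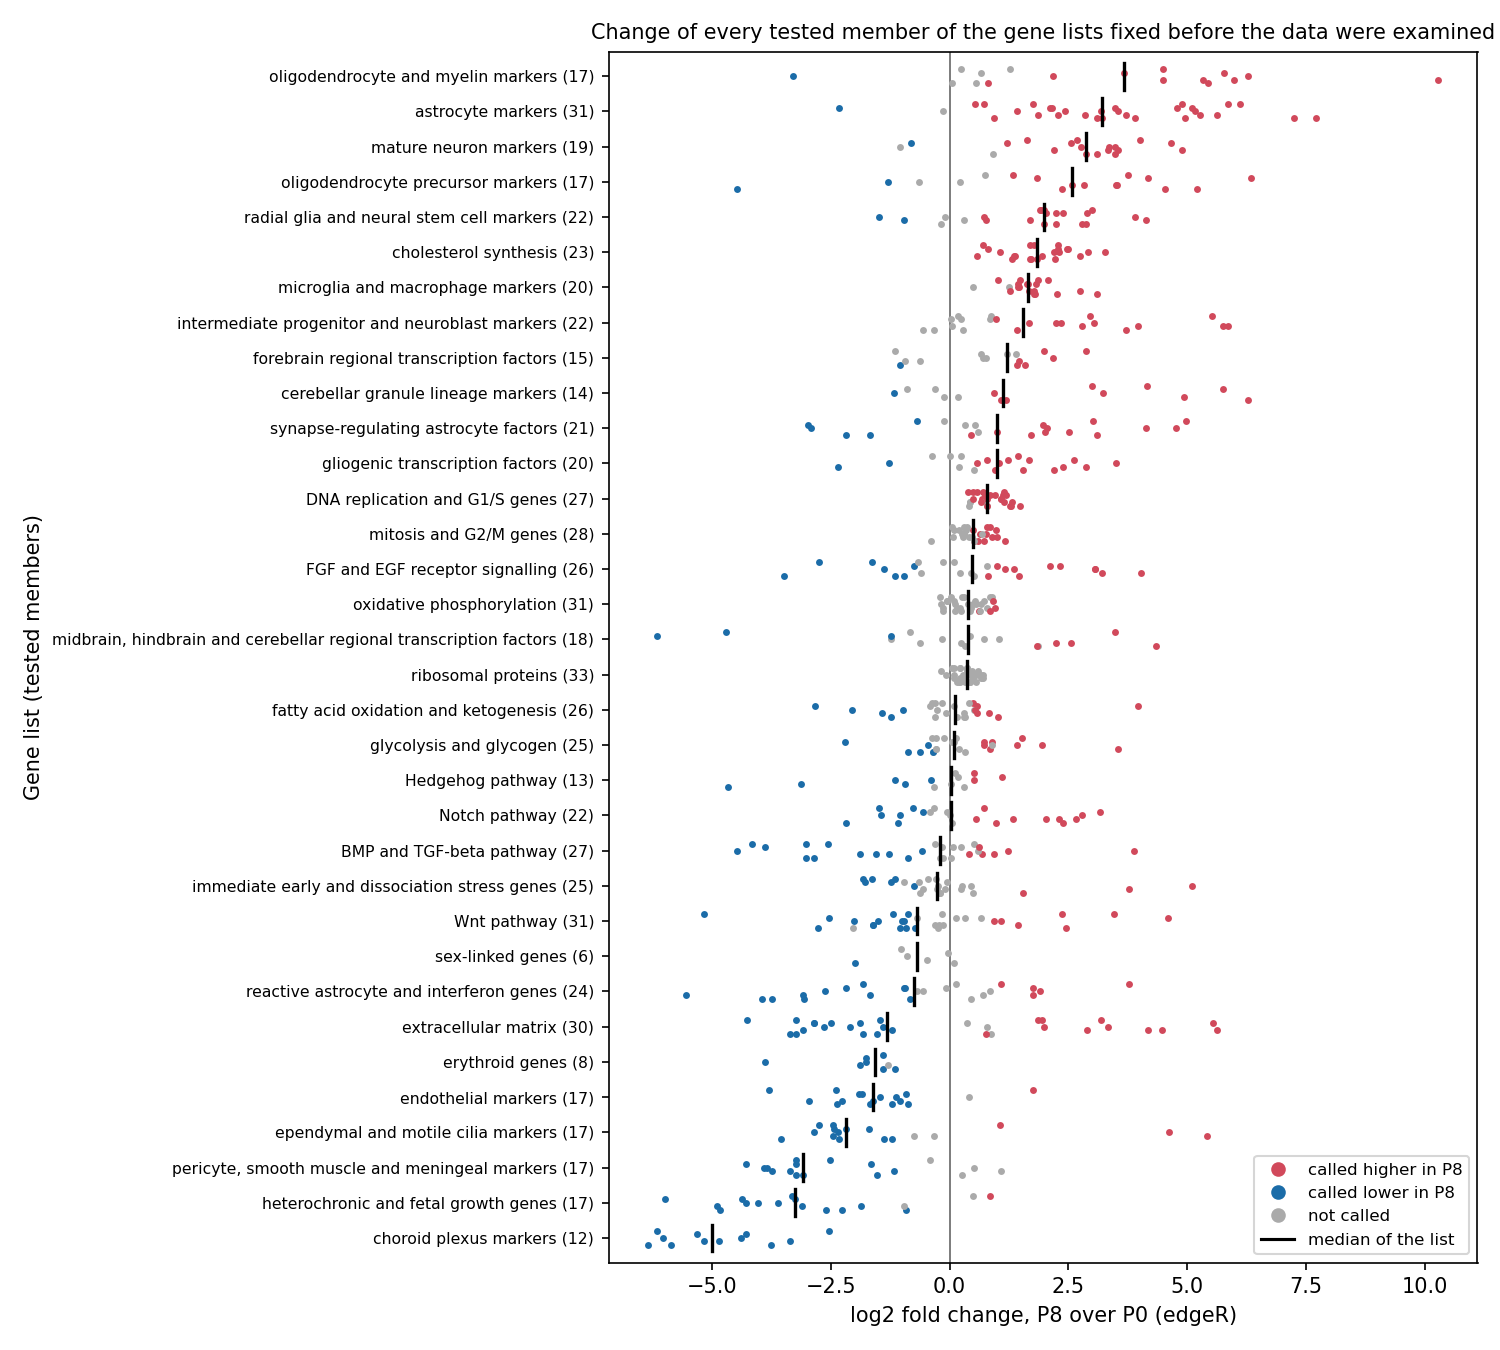
log2 fold change of each tested member of the 34 gene lists, P8 over P0, with genes called higher in red, called lower in blue and not called in grey, and a bar at each list's median. The medians run from -5.01 for choroid plexus markers to 3.68 for oligodendrocyte and myelin markers.

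Stress and reactive genes went both ways. Immediate early and dissociation stress genes gave 3 higher and 6 lower of 25 (3 and 5 adjusted over the list alone; camera adjusted p = 0.309). The inducible heat shock genes Hspa1a and Hspa1b rose from 12.1 ± 2.98 to 158 ± 98.6 CPM and from 5.57 ± 1.48 to 183 ± 111 CPM. They are close copies of each other, so reads could have been split between them. Fosl2 fell from 119 ± 53.4 to 31.6 ± 9.67 CPM and Socs3, a feedback inhibitor of STAT signalling, from 295 ± 117 to 80.7 ± 31.1 CPM. Reactive astrocyte and interferon genes gave 5 higher and 12 lower of 24, the same adjusted over the list alone (camera adjusted p = 0.0764). At the preset correlation this list was called lower without P0 3 (camera adjusted p = 0.0398), without P8 2 (0.0452) and without P0 2 and P8 2 together (0.0474, chosen after the result was seen). With DESeq2 it was also called lower (preranked camera adjusted p = 0.0183, preset correlation). With an estimated correlation and all 8 libraries its camera adjusted p was 0.592. Steap4 fell from 48.9 ± 11.5 to 0.97 ± 0.62 CPM, and the protease inhibitor gene Serpina3n rose from 1.98 ± 1.9 to 26.1 ± 2.38 CPM (1.14 CPM at P0 without P0 3).

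Regional transcription factor lists were not called on the edgeR fit of all 8 libraries. Forebrain genes gave 6 higher and 1 lower of 15, the same adjusted over the list alone (camera adjusted p = 0.0834), and were called higher without P0 4 (camera adjusted p = 0.0361) and, with 5 members left, at a mean of at least 5 CPM (0.0336), both at the preset correlation. With an estimated correlation and all 8 libraries the camera adjusted p was 0.744. Emx2 rose from 3.18 ± 1.46 to 11.9 ± 1.87 CPM. Midbrain, hindbrain and cerebellar genes gave 5 higher and 3 lower of 18, the same adjusted over the list alone (camera adjusted p = 0.406). Irx1 rose from 1.14 ± 0.6 to 12.2 ± 1.31 CPM, Pax2 from 0.291 ± 0.166 to 5.71 ± 4.06 CPM (3.77 CPM at P8 without P8 3), and Lmx1a, a gene of the roof plate and choroid plexus epithelium, fell from 67.8 ± 23.3 to 0.91 ± 0.84 CPM (0.495 CPM at P8 without P8 4). Of 6 tested sex-linked genes 1 was lower, also adjusted over the list alone (camera adjusted p = 0.309), namely Ddx3y at 73.5 ± 12 and 17.5 ± 7.6 CPM. Xist and Y-linked genes were both read in every library, with at least 5861 and 272 counts. This argues against libraries made from 1 animal each. Xist was lowest in P0 1 (120 CPM) and P8 1 (212.5 CPM) and highest in P0 2 (993 CPM) and P8 4 (601.5 CPM). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty all ran the other way. Eif2s3y stood at 47.9 and 32.7 CPM in P0 1 and P8 1, and at 11.4 and 10.9 CPM in P0 2 and P8 4. These values argue against the libraries of an age being technical replicates of a single pool. Over all 34 lists, camera at its preset correlation called 13 up and 6 down, and with an estimated correlation it called 0 (adjusted p from 0.106 to 0.922, with 2 lists at an unadjusted p under 0.05). At the preset correlation, 11 of the 35 splits of the 8 libraries into 4 and 4, the real one included, gave at least as many called lists. The others among these 11 kept part of the age difference. Splits with equal numbers of each age in both groups called at most 15.

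The largest rises outside the paragraphs above belonged to genes of several cell types. Myoc, which encodes myocilin and overlaps a gene on the other strand, rose from 0.395 ± 0.227 to 42.4 ± 15.9 CPM. Hsd11b1, whose enzyme regenerates active glucocorticoid, rose from 0.731 ± 0.276 to 51.5 ± 10.6 CPM and the NMDA receptor subunit gene Grin2c from 0.525 ± 0.329 to 38.6 ± 4.82 CPM. Ppapdc1a rose from 0.171 ± 0.221 to 13.6 ± 0.69 CPM, Lhx1 from 0.135 ± 0.103 to 10.2 ± 5.12 CPM, the myelin lipid enzyme gene Ugt8a from 0.696 ± 0.267 to 41.8 ± 22.2 CPM and St18 from 0.372 ± 0.283 to 22.9 ± 10.5 CPM. Among the falls, Ano9 had 3702 counts at P0 and 3 at P8, a ratio of 1913 with a 95% exact binomial counting interval from 654 to 9280. It lies on chromosome 7 at 148287118 to 148303705. Clec3a fell from 20.7 ± 12.2 to 0.0236 ± 0.0471 CPM, the dipeptidase gene Dpep1 from 35.3 ± 12.5 to 0.071 ± 0.0903 CPM, the protease gene Klk4 from 36.7 ± 7.06 to 0.136 ± 0.126 CPM and Pde6c, a phosphodiesterase gene known from cone photoreceptors, from 12.5 ± 7.03 to 0.0474 ± 0.0316 CPM. Lrg1, Tcf21, Myom2 and Gpihbp1 had means of 12.5 to 23.7 CPM at P0 and of 0.0631 to 0.199 CPM at P8. Wfikkn2 fell from 818 ± 343 to 5.53 ± 2.98 CPM, the tight junction gene Cldn1 from 364 ± 144 to 2.56 ± 2.19 CPM and the melanosome gene Oca2 from 89.3 ± 20.7 to 0.73 ± 0.64 CPM. Some of these low means rested on 1 library. Without P8 4 the P8 means were 0.0318 CPM for Dpep1, 0.0815 CPM for Klk4, 1.51 CPM for Cldn1, 0.421 CPM for Oca2 and 0 for Clec3a. Without P8 2 they were 0.0367 CPM for Lrg1 and 0 for Ano9, and without P0 4 the P0 mean of Ppapdc1a was 0.0732 CPM. Each of these genes was called by edgeR with an adjusted p of 0.00018 or less.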

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

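The tests of the 3 patterns weighed here were all chosen after the result was seen. A library was marked where its gap to the nearest library of its age, divided by the range of the 4, exceeded Dixon's 95% critical value for 4 values. Of 300 groups of 4 values (150 named genes at both ages) 23 were marked (7.67%), and of 68 groups of list means 6 were. Chance marks about 1 in 20 groups.

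P8 2 stood low for neuronal lists, with a mean log2 CPM of 2.29 for mature neuron markers, where the nearest P8 library had 4.15, and of 2.71 for intermediate progenitor and neuroblast markers, where the nearest had 4.02. The same library was high for reactive astrocyte and interferon genes (4.05, nearest 3.56), for Slc1a3 (5030 CPM, nearest 3920) and for Gpr37l1 (728 CPM, nearest 628). Against the mean of the other P8 libraries, its myelin list differed by -1.53 on the log2 scale, its ependymal list by -1.08 and its astrocyte list by 0.16. Its midbrain, hindbrain and cerebellar list differed by -1.13 and its forebrain list by -0.516. Its endothelial list differed by 0.542, its erythroid list by 0.782 and its microglia list by 1.22. Depth of that library does not account for this, since 2 of the other P8 libraries had a lower total. A mislabelled P0 library is argued against by the choroid plexus list, which lay at -4.82 (log2) relative to the lowest P0 library. Fewer neurons and oligodendrocytes carried through the sort may account for the low neuronal and oligodendrocyte lists, though not for the microglia, erythroid or ependymal lists. Of the 88 tested members of the neuron, neuroblast, granule, precursor and myelin lists, 80 (90.9%) lay below every other P8 library, against 25% by chance and 3.23% of 31 astrocyte markers. With a minimum of 10 CPM in the other P8 libraries, used at first, it was 61 of 69 (88.4%). The lists that showed the pattern were the ones tested, and as the library is 1 of 4 replicates no biological explanation was tested.

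Choroid plexus transcripts were higher in every P0 library, with a median log2 fold change of -5.01 at P8. The 20 highest genes of a library held 7.74% to 11.4% of its counts, too little for a change of this size. This argues against a few abundant genes taking the counts. Leaving the 20 genes with the highest mean and the erythroid genes out of library totals left 12 of 12 markers called lower at P8. Those shares made that outcome near certain, so it adds little. Cells of the choroid plexus carried through the sort are a candidate explanation. P8 4 and P8 3 differed 17-fold in Ttr (2990 and 176 CPM), and the 11 other markers were all higher in P8 4. Their median was 2.3 on the log2 scale (0.79 to 4.15), and 2.56 for the 10 at 1 CPM or more in P8 4, a minimum used at first. A source that brings its transcripts together would give such a rise, although the ratio was not the same for every gene. However, P8 4 and P8 3 had the highest and lowest P8 means of this list (4.19 and 1.74 log2 CPM). A rise of most members was therefore near certain, and it does not decide for carried cells. A change with age in what the GLAST-positive cells themselves express cannot be told apart from carried cells. Bulk libraries do not separate expression by the sorted cells from cells carried along, so such a change stays open and untested.

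Of the astrocyte markers 29 of 31 were higher at P8, as were 22 of 27 replication genes and 12 of 28 mitosis genes, while the choroid plexus, vascular and meningeal lists fell, so a larger share of those cells at P0 could lower all other genes there. For astrocyte markers, a share that lowered the astrocyte and radial glia lists alike is argued against as the whole cause. Within a library, the radial glia list was subtracted from the astrocyte list (mean log2 CPM, the 1 shared gene left out). The result was 0.82 ± 0.36 at P0 and 2.54 ± 0.18 at P8 (SD, n = 4), a difference of 1.72 with no overlap. That difference restates the larger rise of the astrocyte list. Other cells that also expressed radial glia markers could raise that list at P0. Of its members 2 fell, so such a share was not excluded. For the cell cycle genes the share cannot be told apart from a rise in proliferation with age. The cell cycle lists (55 genes) minus the radial glia list went from -1.06 ± 0.60 to -2.12 ± 0.12, a difference of -1.05 that restates the smaller rise of those lists and decides neither. With an estimated correlation the replication and mitosis lists were not called (camera adjusted p = 0.483 and 0.613), and genes of both are also expressed by the other cells in the libraries.

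P0 1 had 11 of the 29 marks. It was high for H19 (2400 CPM, nearest 998), Cldn11 (930 CPM, nearest 381), Cdkn1c (880 CPM, nearest 398), Gjb6 (307 CPM, nearest 126), Bmp4 (155 CPM, nearest 89.6) and Lhx6 (7.7 CPM, nearest 4.83), and for the glycolysis and glycogen list (7.6, nearest 7.23). It was low for Pax6 (4.25 CPM, nearest 18.7), Rfx4 (8.79 CPM, nearest 19.4), Barhl1 (0.329 CPM, nearest 1.6) and the midbrain, hindbrain and cerebellar list (-0.78, nearest 0.509). Among lists without a mark, P0 1 was the highest P0 library for the pericyte, smooth muscle and meningeal list (7.61, others 6.58 to 6.93). It was the lowest for the radial glia list (4.97, others 5.58 to 5.87). P0 2 was low for Cpe (312 CPM, nearest 384) and high for Mobp (0.195 CPM, nearest 0.0185), and P0 4 was low for Pfkp (157 CPM, nearest 214).

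Among the other P8 libraries, P8 1 was low for Anpep (4.99 CPM, nearest 12.2) and Dll4 (6.86 CPM, nearest 11.9). P8 3 was low for Apoe (7530 CPM, nearest 11000) and high for Lcn2 (0.348 CPM, nearest 0.213) and the FGF and EGF receptor list (4.71, nearest 4.5). P8 4 was high for Lmx1a (2.17 CPM, nearest 0.602), Rspo3 (2.7 CPM, nearest 2.01) and Clec3a (0.0942 CPM, where the other P8 libraries had 0 counts). P8 2 was high for Ano9 at 0.0427 CPM, which is 3 counts where the others had 0, and low for Pde6c (0 CPM, nearest 0.0628).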

How the results depend on the processing

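Leaving out P0 2 and P8 2 together was the only alternative chosen after the result was seen. The number of genes called stayed within 1.5 times 8321 in every alternative that kept the test against no change, from 6619 with a mean of at least 5 CPM (12579 genes tested) to 9382 with DESeq2. Without filter 8403 genes were called, with DESeq2 size factors 8313, with totals that left out the erythroid and 20 highest genes 8254, with limma-voom 8482, and without P0 2 and P8 2 together 7964. Leaving out each library in turn gave 6979 to 8360 genes (3395 to 4151 higher and 3584 to 4209 lower), and 4929 to 5554 with at least a 2-fold change. No gene was called in opposite directions between the reported fit and any alternative. The share of calls that were higher at P8 was 49.4%, and lay between 43.3% (totals without the highest genes) and 50.5% (limma-voom). A test against a 1.5-fold change called 5026 genes, fewer because it asks for a larger change. Slc1a3 had a log2 ratio of mean CPM of 3.81, and of 3.90 after TMM and 3.87 after median-of-ratios scaling.

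The replicate numbers did not pair the libraries. Correlations of the deviations of same-numbered libraries from their age means were -0.131, -0.0563, 0.0641 and 0.0456, and own numbers gave the highest correlation for 1 of 4. With the replicate number as a block 7355 genes were called (3638 higher and 3717 lower), 5016 with at least a 2-fold change, and 22 lists (15 up and 7 down), the 3 gained being oxidative phosphorylation (up, camera adjusted p = 0.0285), ribosomal proteins (up, 0.0473) and reactive astrocyte and interferon genes (down, 0.0473). Without the block and with an estimated correlation their adjusted p was 0.78, 0.78 and 0.592.

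Of 35 splits of the 8 libraries into 4 and 4, only the real one gave as many calls (1 of 35 for 8321 genes and 1 of 35 for 5291 with at least a 2-fold change). The highest of the other splits gave 0 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 the highest gave 1509, against 9398 in the real one. The other splits mix the ages, so the difference between ages adds to the spread within their groups. Their counts therefore do not measure what chance gives, and 1 of 35 is the smallest share that 35 splits allow. For the lists, 11 of the 35 splits called at least 19 with camera at its preset correlation, and the highest of the others called 23. Every other split with at least 19 differed from the real one by 1 exchanged library of each age, and so kept part of the age difference. Splits with equal numbers of each age in both groups called at most 15. Chance is therefore neither measured nor excluded for the lists by these splits. With an estimated correlation 0 lists were called, 0 up and 0 down, where 19 (13 up and 6 down) were called at the preset one. The preset calls ranged from 19 to 23 lists in the other alternatives. They depend on the preset because members of a list vary together between libraries of one age (estimated correlation up to 0.98, for ribosomal proteins).

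For the 219 named genes, 1661 of 1752 calls in the fits that left out 1 library were on the same side of the threshold as reported, 90 were lost and 1 was gained. In the other settings 1698 of 1736 were the same, 37 were lost and 1 was gained. No called gene or list changed direction. Depth limits the statements about genes near the floor of 3 counts, such as Ano9 and Clec3a at P8.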

Other observations

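Gene families defined by the start of the symbol were compared with all tested genes after the results were seen. There were 404 one-sided Fisher's exact tests (202 families of at least 10 tested genes, both directions), of which 5 had an adjusted p under 0.05. The tests treat genes as independent, although members of a list varied together between libraries of one age. Their p-values therefore do not measure the spread between libraries. Collagen genes (symbols starting Col) were concentrated among the falls, with 32 of 44 lower at P8 and 1 higher, against 25% of all tested genes lower (odds ratio 8.03, adjusted p = 1.64e-08), and annexin genes gave 9 of 10 lower (odds ratio 27, adjusted p = 0.00302). In the same libraries 13 of 17 pericyte, smooth muscle and meningeal markers (median 8.5-fold lower) and 15 of 17 endothelial markers were lower, as were 12 of 12 choroid plexus markers, and 16 of 19 mature neuron markers were higher. The clustered protocadherins of the gamma A group (Pcdhga), neuronal and glial adhesion molecules that share their constant exons, gave 12 of 12 higher, against 24.5% of tested genes (adjusted p = 9.15e-06), with a median log2 fold change of 1.23. Because those genes share exons, their counts are not independent of each other. Protocadherins with symbols of Pcdh and a number gave 9 of 12 higher and 2 lower (adjusted p = 0.0263), while the clustered alpha (Pcdha) and beta (Pcdhb) groups gave 1 of 13 and 1 of 21 higher (adjusted p = 1 for both) and 0 lower. Solute carriers (Slc) gave 109 of 302 lower (36.1%, adjusted p = 0.00148) and 93 higher (30.8%, adjusted p = 0.203).

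The gene classes deposited with the table were compared in the same way (15 classes, 30 tests). These tests also treat genes as independent, so their p-values do not measure the spread between libraries. Ion channel genes were concentrated among the rises, with 105 of 278 higher (37.8%, odds ratio 1.9, adjusted p = 1.38e-05) and 70 lower, as were G-protein coupled receptors with 83 of 263 (adjusted p = 0.022) and enzymes with 703 of 2540 (adjusted p = 0.000422). Transporters gave 251 of 883 higher (28.4%, adjusted p = 0.0154) and 248 lower (28.1%, adjusted p = 0.056). Growth factors gave 39 of 97 lower (40.2%, odds ratio 2.02, adjusted p = 0.00533), kinases 209 of 673 (adjusted p = 0.00192), peptidases 128 of 402 (adjusted p = 0.00679) and ligand-dependent nuclear receptors 17 of 38 (adjusted p = 0.024). Transcription regulators were called lower in 24.2% and higher in 22.4% of 1199 genes, close to all tested genes. The marker lists moved beside these classes, with mature neuron markers a median of 7.33-fold and microglia markers 3.17-fold higher, and choroid plexus markers 32.2-fold and meningeal markers 8.5-fold lower.

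In P0 2 the 33 ribosomal protein genes lay below the mean of the other P0 libraries by a median of -1.47 on the log2 scale (-2.42 to -0.674), and this library had 1.22% of its counts in the ribosomal RNA gene Rn45s, against 0.0672% to 0.126% in the other P0 libraries. That share lowers every other gene by 0.018 on the log2 scale, too little to account for the median. Across genes, which are not independent replicates, the deviation of a library had a correlation with log2 gene length of 0.337 in P0 2 and -0.342 in P0 4. A set of 164 other genes nearest in length and level deviated by a median of -0.534, but their median length was 1510 bases against 778 for the ribosomal protein genes, so they were not a close match.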
